A study of Gallus gallus with 24 samples.

How the data were processed

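RNA was sequenced from gonads of chickens with a disrupted DMRT1 gene and of controls. DMRT1 is a Z-linked transcription factor of the male gonad. The 24 libraries form 8 groups of 3, given by sex, by disruption and by time. The times are embryonic day 6 (E6) and a later time, for which the sample titles give an age of 1 day and the time characteristic gives 1 week. It is called the later time here, and the conflict was left open. Titles also differ between the times: controls are WT at E6 and WL later, and disrupted females are DMRT1 at E6 and DMRT1-KI later, while disrupted males are DMRT1-KI at both. What these titles stand for beyond the groups was not used. Per the labels, total RNA was made into strand-specific mRNA libraries and sequenced as paired-end reads of 100 bp on an MGIseq instrument.

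Per the labels, the authors used Trimmomatic, HISAT2 and featureCounts with the genome build galGal6. The deposited files hold raw counts of read pairs per Ensembl gene, with no normalization. Per the file headers, the counts came from featureCounts version 2.0.0 in paired and reverse-stranded mode (strand setting 2) with the Ensembl annotation of release 98. Each file holds 24356 genes, with whole numbers only and a different total in every file. Totals ran from 17376463 to 102629185 counts per library. No unique molecular identifiers are described in the labels, so intervals and floors cover counting error only.

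Gene symbols were not used. The files do not pair the Ensembl IDs with symbols, and 0 of the 24356 IDs matched the reference table supplied with the files. The 20 gene lists fixed before the data were examined, the check of DMRT1 in each library and the part of the naming rule that needs symbols were therefore not analysed here. The rule for named genes was kept without its symbol requirement and limited to 2 IDs per direction and disruption comparison. It takes the largest log2 fold each way among genes with an adjusted p under 0.05, a mean of at least 5 CPM (edgeR's unit of counts scaled to the effective library size) in the higher group and no overlap of CPM between the groups. This departs from the rule as fixed.

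Counts were analysed in R 4.3.3 with edgeR 4.0.16. All 24 libraries entered 1 model with 8 group means, without a replicate term. Genes were kept by filterByExpr with the groups, which left 17846 genes, of which 16689 were autosomal, 873 on Z, 81 on W and 27 mitochondrial. Libraries were scaled by TMM, dispersions were estimated robustly and contrasts were tested with the two-sided quasi-likelihood F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, within each comparison. The 16 comparisons were disruption within each sex and time, sex within controls and within disrupted gonads at each time, disrupted males against control females at each time, time within controls of each sex, and the interactions of disruption with sex and with time.

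Sex programmes were the autosomal genes called between control females and control males of the same time with at least a 2-fold difference. The sex score of a library is the mean log2 CPM (prior count of 2) of the genes higher in control females minus that of the genes higher in control males. It was scaled so that the control males of that time average 0 and the control females average 1. Scores, detected genes and chromosome shares were compared with two-sided exact permutation tests, whose smallest p with 3 against 3 libraries is 0.1. Detected genes at the later time were counted after thinning every library to 18476158 counts. Overlaps of gene lists and shares per chromosome used Fisher's exact test over the genes tested.

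Since the control libraries choose the programme genes and also serve as the comparison, 20 data sets with no effect of disruption were simulated and passed through the same steps. In these and in the data with known folds below, each gene was drawn on its own. The simulated libraries thus carry no variation shared between genes, and their ranges may be too narrow and their error rates too low. The tests were also tested on simulated data with known folds in 100 genes per fold. In the 4 disruption comparisons, 33% to 46% of 2-fold changes and 80% to 95% of 4-fold changes were recovered, and 2.94% to 5.83% of the calls were false. Where all libraries of a group had 0 counts of a named gene, the fold was bounded with a floor of 3 counts over the group. Medians of gene lists were also computed with such genes at their bound. Identical libraries were looked for by the spread of counts between replicates, and none were found: the median chi-square of replicate pairs was at least 1.56, where resequencing of 1 library gives 0.455.

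The alternatives fixed before the data were examined were RLE size factors, TMM on autosomal genes, no filter on low counts, a replicate block, DESeq2 1.42.0, fits on the 12 libraries of a time or on the groups compared, other definitions of the sex score, and leaving out each library in turn. Those added after seeing the data were scaling by library sizes only, leaving out mitochondrial genes, and treating as a series the 3 later control libraries (males 1 and 3, female 1) whose titles lack a suffix carried by the other 9 later libraries. This series was either left out, which leaves 1 control male library, or entered as a term. Leaving control libraries out of the scores was added too. For programme counts, genes lower in both sexes at E6, correlations and Z shifts, none of the alternatives was fixed beforehand. Nor were scores under other scalings, without the filter or on the 12 libraries of a time.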

Results

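Gene expression was measured in 24 gonad RNA-seq libraries from male and female chickens with or without a disruption of DMRT1, at E6 and at a later time, with 3 libraries in each of 8 groups. Total counts ran from 23017339 to 42511285 in E6 males, from 17376463 to 102629185 in E6 females and from 18476158 to 26858683 at the later time. The deepest library was disrupted female replicate 2 at E6. Genes of the W chromosome, which only females carry, summed to between 15.3 and 47.2 CPM in the male libraries and between 2675 and 3979 CPM in the female libraries, so every library matched the sex of its group. Genes are given by their Ensembl IDs, with positions in GRCg6a.

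Late male gonads with disrupted DMRT1 were compared with control males to ask how the male gonad depends on this gene. Of 17846 genes tested, 3965 were higher and 3631 lower in disrupted males. The higher genes moved further, with a median log2 fold of 2.02 and 1217 genes at least 8-fold higher, against a median of -0.94 and 249 genes at least 8-fold lower. With the 101 and 14 genes that had 0 counts in a group placed at their bound, these medians were 2.01 and -0.94. A set of 270 genes lay under 0.1 CPM in control males and at 1 CPM or more in disrupted males, and 198 of these were at 1 CPM or more in control females. The reverse, on in control males and off in disrupted males, held for 29 genes. On the mitochondrial genome, 16 of 27 genes were higher, and the mitochondrial share of counts was 19.4% ± 2.42 (SD, n = 3) in disrupted and 11.4% ± 2.46 (SD, n = 3) in control males, with an exact permutation p of 0.1. The number of genes detected after thinning to equal counts was 20262 ± 214 in disrupted and 19280 ± 583 in control males (SD, n = 3), again with an exact permutation p of 0.1.

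Named by the rule, ENSGALG00000053928 (Z, 73031106 to 73041048) had 23.2 ± 2.97 CPM (SD, n = 3) in disrupted males and 0 counts in the 3 control males, which makes it at least 579-fold higher. ENSGALG00000048408 (chromosome 12, 7371428 to 7407730) had 6.46 ± 1.03 CPM (SD, n = 3) and again 0 counts in controls, at least 161-fold higher. Among lower genes, ENSGALG00000010596 (chromosome 4, 39167827 to 39202586) fell by 7.94 ± 0.91 on the log2 scale (SE), from 12.9 ± 10.02 to 0.0485 ± 0.0207 CPM (SD, n = 3). ENSGALG00000054606 (chromosome 4, 67258854 to 67338731) fell by 7.01 ± 0.68 (SE), from 48.3 ± 27.6 to 0.368 ± 0.248 CPM (SD, n = 3). The edgeR adjusted p was 1.44e-06 and 1.88e-07 for these 2 lower genes, and 4.37e-08 and 4.02e-07 for the 2 higher ones.

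Control gonads of the later time differed widely between the sexes. Females were higher than males for 3665 genes and lower for 3253. The W chromosome had 71 genes higher and 1 lower in females, and the Z chromosome, present in a double dose in males, had 463 genes lower and 76 higher. Among autosomal genes with at least a 2-fold difference, 2775 were higher in females and 1305 higher in males, and these are the female and male programmes of the later time. Control females also had 1010 more genes detected after thinning than control males (exact permutation p of 0.1). With scaling by library sizes only, chosen after seeing the data, the split over all genes was 4174 higher and 2452 lower. Fitted on the compared groups alone, the test called 3802 genes.

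Most of the female programme was up in late disrupted males and most of the male programme was down. Of the 2775 female programme genes, 2444 (88.1%) rose in disrupted males, with a median log2 fold of 2.40 over all of them, or 2.39 with genes at 0 counts at their bound. Of the 1305 male programme genes, 1177 (90.2%) fell, with a median log2 fold of -1.74. Over 16689 autosomal genes, the folds of disruption in males followed the folds of sex in controls with a Pearson r of 0.935, a Spearman rho of 0.899 and a slope of 0.972. The same controls enter both folds, and genes are not independent replicates. Simulated data without an effect gave a mean r of 0.162, and the covariance was 2.54 against a simulated mean of 0.142. The sex score of disrupted males was 0.983 ± 0.0145 (SD, n = 3), where control males averaged 0 and control females 1, and simulated unchanged males averaged 0.0426. The exact permutation p against control males was 0.1, the smallest possible. Control males spread more than the other late groups, with an SD of 0.137, through replicate 2. This library scored -0.158, where replicates 1 and 3 scored 0.0782 and 0.0796, and had a mitochondrial share of 8.63%, where they had 12.1% and 13.4%. It is also the only late control male whose title carries the suffix, so its distance from the others and the title series cannot be told apart.

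**Figure D1:**
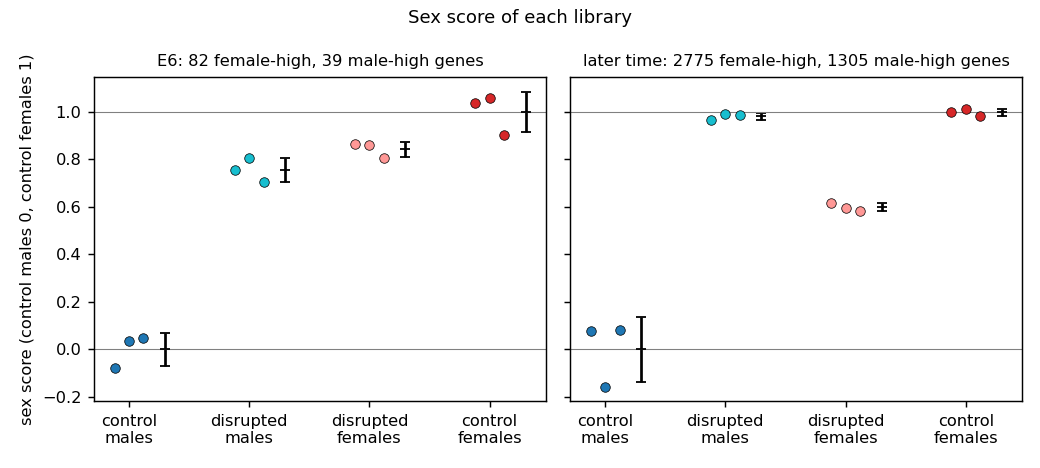
Sex score of each library at E6 and at the later time, on a scale where control males average 0 and control females average 1; points are libraries, with 3 per group. At the later time disrupted males average 0.983 and disrupted females 0.599.

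**Figure D2:**
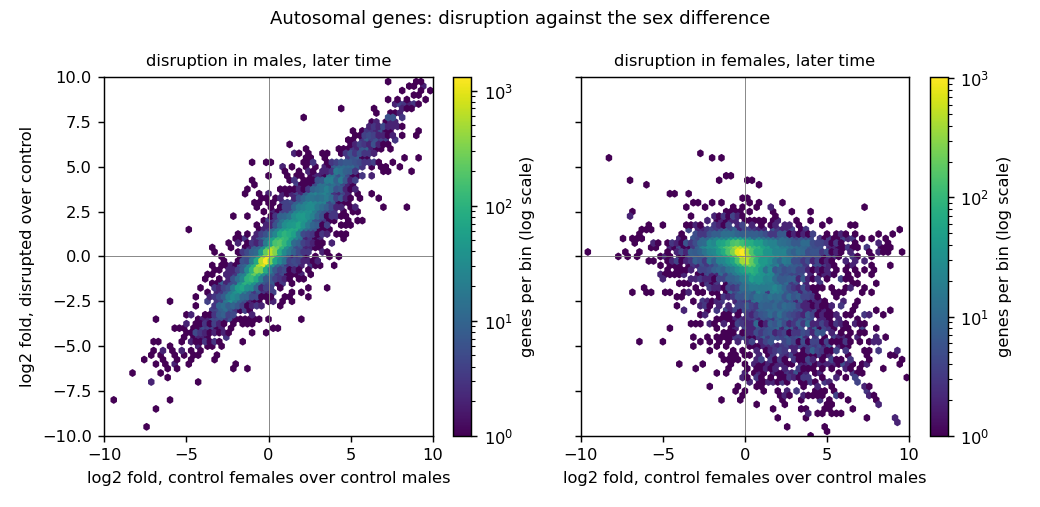
Log2 folds of autosomal genes at the later time, control females over control males on the horizontal axis and disrupted over control gonads on the vertical axis, with shading by the number of genes per bin on a log scale. Male disruption folds follow the diagonal (Pearson r of 0.935), and female disruption folds run the other way (r of -0.497). Control libraries enter both axes, and simulated data without an effect gave a mean r of 0.162 in males and -0.137 in females.

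Late disrupted males were then compared directly with control females. Of 17846 genes, 274 were higher and 194 lower in disrupted males. These sat mostly on the sex chromosomes: on Z 244 genes were higher and 2 lower, on W 65 were lower, and on autosomes 30 were higher and 126 lower. Within the female programme 2701 genes (97.3%) did not pass this test, nor did 1300 (99.6%) of the male programme, which does not show that their levels were equal. The total of 468 genes became 293 without disrupted male replicate 2, and 775, 279 and 257 without control female replicates 1, 2 and 3. Without control female replicate 1 the balance turned over, to 370 higher and 405 lower. It was also 293 in the fit on the 12 libraries of the time, 275 on the compared groups, 750 with DESeq2, and 1042 or 914 with the 3 libraries lacking the title suffix left out or set apart by a term, the last 2 settings chosen after seeing the data.

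Late female gonads with disrupted DMRT1 were compared with control females, which carry 1 Z chromosome, to ask whether the ovary depends on DMRT1 too. They had 2850 genes lower and 1292 higher than controls. The lower genes moved much further, with a median log2 fold of -2.45 and 1176 genes at least 8-fold lower, against a median of 0.63 and 12 genes at least 8-fold higher. With 195 lower genes at 0 counts placed at their bound, the median of the lower genes was -2.42. A set of 275 genes was at 1 CPM or more in control females and under 0.1 CPM in disrupted females, and no gene went the other way by this measure. Of these 275 genes, 214 were at 1 CPM or more in late disrupted males and 7 in E6 control females. The number of genes detected in thinned libraries was 18610 ± 211 in disrupted and 20290 ± 122 in control females (SD, n = 3), with an exact permutation p of 0.1.

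The count of higher genes in late disrupted females moved with the scaling, the filter and the libraries used. It was 641 against 3173 lower genes with TMM on autosomal genes and 754 against 3155 without the filter on low counts. Chosen after seeing the data, scaling by library sizes only gave 317 against 3664, and leaving out the libraries without the title suffix gave 546 against 3226. Without disrupted female replicates 1 and 3 there were 838 and 644 higher genes, and without control female replicates 1 and 2 there were 606 and 784. TMM on autosomal genes shifted the median log2 fold of all genes by -0.10 and library sizes only shifted it by -0.21, so the small rises are relative to the scaling. In males, library sizes only shifted that median by 0.12.

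ENSGALG00000008941 (chromosome 1, 22977640 to 22983971) had 7.26 ± 4.66 CPM (SD, n = 3) in late control females and 0 counts in disrupted females, which makes it at least 157-fold lower (edgeR adjusted p of 9.33e-06). ENSGALG00000009640 (chromosome 5, 30281791 to 30329607) had 5.93 ± 1.33 CPM (SD, n = 3) in controls and 0 counts in disrupted females, at least 128-fold lower (edgeR adjusted p of 2.44e-06). The higher genes named by the rule were ENSGALG00000003226 (chromosome 26, 4710399 to 4718290), at a log2 fold of 2.17 ± 0.37 (SE), and ENSGALG00000014835 (Z, 12908352 to 12956390), at 2.06 ± 0.38 (SE). They had 15.2 ± 2.52 and 118 ± 35.3 CPM in disrupted females, and 3.38 ± 0.911 and 28.3 ± 9.84 CPM in controls (SD, n = 3).

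A large part of the female programme was lost in late disrupted females. Of the 2775 genes, 1389 (50.1%) fell, 68 rose and 1318 were not called. The fallen genes had a median log2 fold of -3.40, or -3.30 with 121 genes at 0 counts at their bound, and 807 of them fell at least 8-fold. Of the 1305 male programme genes 160 rose, 34 fell and 1111 were not called. Their median log2 fold was 0.41, where that of all autosomal genes was 0.07. Of the 1292 genes higher in disrupted females, 590 were lower in control females than in control males, again with control females in both lists. The sex score of disrupted females was 0.599 ± 0.0164 (SD, n = 3) against 1 ± 0.0146 (SD, n = 3) in control females, with an exact permutation p of 0.1, and simulated unchanged females averaged 0.958. Over all genes tested, 1725 of the 2850 genes lower in disrupted females were higher in control females than in control males. The late control females enter both lists, so no chance value is given. Male and female disruption folds ran in opposite directions across autosomal genes, with a Pearson r of -0.448 and a Spearman rho of -0.350, and 1765 genes were both higher in disrupted males and lower in disrupted females, where chance gives 633. The interaction of disruption with sex was called for 7872 genes.

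The genes lost in disrupted females were set against changes with age. In control females 5491 genes rose and 4343 fell between E6 and the later time, and in control males 4665 rose and 3890 fell. Controls are titled WT at E6 and WL at the later time, so in controls time and this change of title cannot be told apart. Of the 2850 genes lower in late disrupted females, 1866 rose with age in control females, whose late libraries enter both lists, so no chance value is given and part of this number comes from the choice of genes. In control males, whose libraries enter neither list, 922 of the 2850 (32.4%) rose with age and 581 (20.4%) fell, and of the 1292 genes higher in disrupted females 454 (35.1%) rose and 283 (21.9%) fell. By control males, then, all 2850 lost genes as a set did not rise with age more often than the genes that were higher. Over all 17846 genes tested, 26.1% rose in control males and 21.8% fell. Lost and higher genes thus both rose more often than genes at large, a difference that was not tested. The genes at least 8-fold lower differed from the 2850 as a whole. Of these 1176 genes, 474 (40.3%) rose with age in control males and 68 (5.78%) fell. Genes at least 8-fold higher were not set against age. Only 6 of the 2850 genes were already lower in disrupted females at E6, where chance gives 11.02.

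**Figure D3:**
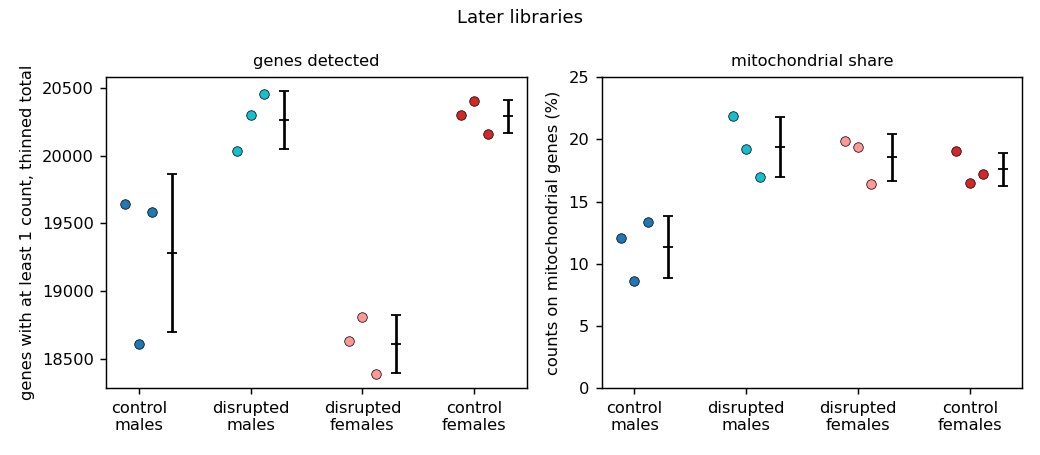
Detected genes after thinning (left) and the share of counts on mitochondrial genes in percent (right) for each library of the later time, with 3 libraries per group. Disrupted females average 18610 detected genes against 20290 in control females, and control males average a mitochondrial share of 11.4%, the lowest of the 4 groups.

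At E6 disruption in males changed few genes, with 30 higher and 110 lower than in control males. Lower genes outnumbered higher ones in every alternative run, but the size of the excess varied. It nearly vanished in the fit on the 12 E6 libraries, at 181 and 183, and was small with DESeq2, at 205 and 296, and without disrupted replicate 2, at 122 and 145. On the compared groups the split was 17 and 126, and without disrupted replicates 1 and 3 and control replicates 1, 2 and 3 it was 9 and 53, 3 and 37, 4 and 38, 3 and 90, and 5 and 76. The lower genes included much of the small male programme of that age: of 39 autosomal genes at least 2-fold higher in control males than in control females, 28 fell in disrupted males, with a median log2 fold of -2.03 over the 39. The E6 control males both choose these genes and are the baseline of the fold, so part of that median comes from the choice, and in simulated data without an effect no male programme gene was called lower. Of 82 genes higher in control females, 8 rose and 74 were not called. The 8 became 5, 5 and 1 without disrupted male replicates 1, 2 and 3, 0, 1 and 3 without control male replicates 1, 2 and 3, and 5 without control female replicate 1, and they were 5 without the filter on low counts, 20 on the 12 E6 libraries and 24 with DESeq2. The 82 genes became 46 and 45 without control male replicates 2 and 3, 48 and 50 without control female replicates 1 and 2, and 144 with DESeq2. The 39 genes became 22 without control male replicate 1, 18, 17 and 23 without control female replicates 1, 2 and 3, and 60 on the 12 libraries. ENSGALG00000050161 (Z, 4342321 to 4353388) fell by 7.72 ± 0.77 on the log2 scale (SE), from 59.9 ± 30.1 to 0.249 ± 0.320 CPM (SD, n = 3; edgeR adjusted p of 2.69e-05). ENSGALG00000010018 (chromosome 1, 35639105 to 35646809) fell by 5.96 ± 0.66 (SE), from 19.3 ± 9.65 to 0.290 ± 0.247 CPM (SD, n = 3; edgeR adjusted p of 6.67e-05). Genes of Z were among the lower genes more often than autosomal genes, with 15 of 873 (1.72%) against 0.563% (adjusted Fisher's exact p of 0.0108).

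The higher genes of E6 males were less stable. ENSGALG00000013294 (chromosome 10, 9662329 to 9683958) had a log2 fold of 6.34 ± 1.18 (SE; edgeR adjusted p of 0.0123), with 11.2 ± 14.8 CPM in disrupted and 0.155 ± 0.121 CPM in control males (SD, n = 3). It missed the threshold in 3 of 15 alternatives. ENSGALG00000029282 (chromosome 9, 5874581 to 5875710) had a log2 fold of 2.65 ± 0.58 (SE; edgeR adjusted p of 0.0340) and missed it in 7 of 15. The 140 genes became 62, 267 and 40 without disrupted replicates 1, 2 and 3, and 42, 93 and 81 without control replicates 1, 2 and 3. The fit on the 12 E6 libraries called 364 and DESeq2 called 501.

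The sex score of E6 disrupted males was 0.756 ± 0.0491 (SD, n = 3), with an exact permutation p of 0.1 against control males, where simulated unchanged males averaged 0.152 and reached at most 0.167. Across autosomal genes the male disruption folds and the sex folds of E6 had a Pearson r of 0.601 and a Spearman rho of 0.555, where simulated data without an effect gave a mean r of 0.292. All 39 genes of the male programme and 70 of the 82 of the female programme did not pass the test between disrupted males and control females. This does not show that their levels were equal. Of the 82 genes, 74 were not called against control males, and 6 were called higher than control males and not called against control females. Of the 39, 28 were called lower than control males and not called against control females. The test against control females called 122 genes higher and 103 lower in disrupted males, 39 of the 225 on autosomes. The balance turned over, to 54 and 85 on the compared groups, 70 and 83 without disrupted male replicate 1, and 71 and 79 or 68 and 103 without control female replicate 2 or 3. The total was 139 on the compared groups alone and 395 with DESeq2. The programmes themselves are small: the 28 fallen male programme genes became 18 and 17 without disrupted male replicates 1 and 3, 11 without control male replicate 1, and 18 and 15 without control female replicates 1 and 2. They were 49 on the 12 libraries and 44 with DESeq2.

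In E6 females, disruption left 69 genes lower and 8 higher than in controls. Of the 82 genes higher in control females than in control males, 17 fell, where simulated data without an effect gave 0. The 17 became 8, 9 and 10 without disrupted female replicates 1, 2 and 3, 7 and 9 without control female replicates 1 and 2, and 31 with DESeq2. Over the whole list of lower genes 20 were higher in control females than in males. The E6 control females enter both lists, so no chance value is given. ENSGALG00000013294, the gene named above as higher in disrupted males, fell by 6.07 ± 0.93 on the log2 scale (SE), from 194 ± 120 to 2.77 ± 1.93 CPM (SD, n = 3; edgeR adjusted p of 0.00242), and missed the threshold in 1 of 15 alternatives. ENSGALG00000049572 (chromosome 6, 12277578 to 12280846) fell by 4.36 ± 0.62 (SE; edgeR adjusted p of 0.000966), from 11.04 ± 2.60 to 0.512 ± 0.266 CPM (SD, n = 3). ENSGALG00000031866 (chromosome 6, 1616246 to 1623255) rose by a log2 fold of 2.10 ± 0.33 (SE; edgeR adjusted p of 0.00285). ENSGALG00000015720 (chromosome 1, 100912368 to 100941544) had a log2 fold of 1.41 ± 0.29 (SE; edgeR adjusted p of 0.0259) and missed the threshold in 5 of 15 alternatives.

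The sex score of E6 disrupted females, 0.843 ± 0.0319 (SD, n = 3), lay within the range of simulated unchanged females, 0.813 to 0.852, while the folds of disruption in E6 females and the sex folds of E6 had a Pearson r of -0.504 and a Spearman rho of -0.314 across autosomal genes, beyond the simulated range of r from -0.349 to -0.317. Their covariance was -0.241, against simulated values from -0.164 to -0.143, with the control females in both folds. Set against these ranges, the score and the folds gave different answers on a shift of E6 females along the sex axis. The simulations leave out variation shared between genes, so the ranges may be too narrow to decide this. Disrupted replicate 3 stood apart from the other disrupted females, with a score on the first principal component of the E6 libraries of 78.4, against -33.0 and -26.9 for replicates 1 and 2. The median chi-square of counts was 1.56 between replicates 1 and 2 and 9.73 and 13.2 between each of them and replicate 3. The 77 genes became 32, 31 and 43 without disrupted replicates 1, 2 and 3, and 32 and 36 without control replicates 1 and 2. They were 120 in the fit on the 12 E6 libraries, 195 on the compared groups and 255 with DESeq2. The interaction of disruption with sex at E6 was called for 22 genes, 19 higher and 3 lower, and the balance turned over to 58 and 160 with DESeq2, and to 15 and 44 or 15 and 34 without disrupted female replicate 1 or 2.

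A small group of 19 genes was lower in disrupted gonads of both sexes at E6, where chance gives 0.425 (Fisher's exact p of 7.15e-27). Their median log2 fold was -1.66 in males and -2.21 in females, and 4 of them lie on Z. In late disrupted males 14 of the 19 were lower and 2 higher, and in late disrupted females 1 was lower, 3 were higher and 15 were not called. In late control gonads 13 of the 19 were lower in females than in males. The 19 genes became 11 without disrupted male replicate 3, 11 without control male replicate 1, 7, 8 and 11 without disrupted female replicates 1, 2 and 3, and 10 and 12 without control female replicates 1 and 2. They were 34 on the 12 E6 libraries and 58 with DESeq2. Of the 110 genes lower in E6 disrupted males, 70 were also lower in late disrupted males, where chance gives 22.4.

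Sex differences of control gonads at E6 were mostly carried by the sex chromosomes. Females were higher than males for 179 genes and lower for 207, with 64 W genes higher, 154 Z genes lower and 6 Z genes higher, and 108 autosomal genes higher and 53 lower. In disrupted gonads of that age, 80 genes were higher and 171 lower in females, of which 27 were autosomal. The balance of that split turned over, to 154 and 112 without disrupted female replicate 1 and 144 and 122 without replicate 2. At the later time disrupted females and males differed at 2239 higher and 3403 lower genes, with 2130 and 2954 on autosomes. That split was 1238 and 3845 with TMM on autosomal genes, 836 and 4141 with library sizes only and 1718 and 4238 without the libraries lacking the title suffix, the last 2 settings chosen after seeing the data. The E6 control split also turned over, to 157 and 128 without control male replicate 1, 175 and 124 without control female replicate 3 and 300 and 276 with DESeq2. The 386 genes of the E6 controls were 246 and 249 without control female replicates 1 and 2, and the 251 of the E6 disrupted gonads were 127 on the compared groups and 481 with DESeq2.

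Dosage of the Z chromosome was described by medians. The median log2 fold of females over males on Z, less the autosomal median, was -0.50 in controls and -0.52 in disrupted gonads at E6, and -0.80 in controls and -0.68 in disrupted gonads at the later time. These differences between controls and disrupted gonads were not tested. Within a sex, the median shift of Z against autosomes with disruption was 0.00 in E6 males, -0.07 in E6 females, 0.02 in late males and 0.06 in late females. In late disrupted females 102 of 873 Z genes (11.7%) were higher, against 7.07% of autosomal genes (adjusted Fisher's exact p of 6.27e-05), and 113 (12.9%) were lower, against 16.2% (adjusted Fisher's exact p of 0.0199). These shares were tested with TMM on all genes only, and the count of higher genes in that comparison moved with the scaling.

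**Figure D4:**
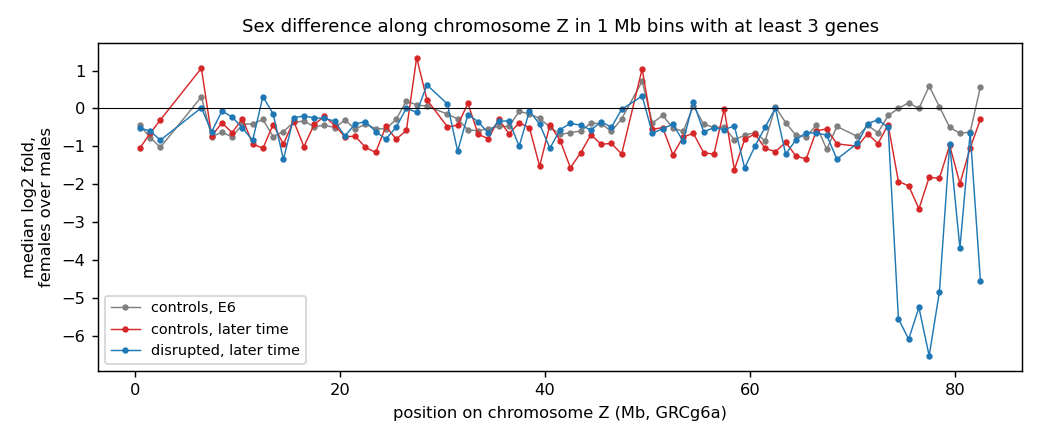
Median log2 fold of females over males in bins of 1 Mb along chromosome Z (position in Mb), for controls and disrupted gonads. Between 27 and 28 Mb the late control median is 1.34 over 20 genes.

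The Z bin between 27 and 28 Mb stood apart in late controls. Its 20 genes had a median log2 fold of 1.34 toward females, with 12 genes higher and 1 lower in control females, while in disrupted gonads the median was -0.10, with 3 higher and 4 lower. With disruption, 9 of the 20 were higher and 0 lower in late males, at a median log2 fold of 0.93. Without 1 gene near 0 counts in both male groups, that median was 0.42. In late females 1 was higher and 1 lower with disruption, at a median of 0.18. At E6 only 2 of the 20 were higher in control females. The bin was singled out after the values were seen.

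The effect of disruption was also tested for a difference between the times. The interaction of disruption with time was called for 4030 genes in males, 2066 higher and 1964 lower, and for 2069 genes in females, 520 higher and 1549 lower. Controls change title from WT to WL between the times, and disrupted females from DMRT1 to DMRT1-KI. A difference between the times and this change of titles cannot be told apart. The female split was 327 and 1713 with TMM on autosomal genes, 173 and 1535 without E6 disrupted female replicate 1 and, chosen after seeing the data, 161 and 2123 with library sizes only. The male split has no firm balance, at 1770 and 1885 without E6 control male replicate 1 and 1651 and 1035 on the compared groups. Fitted on the compared groups alone, the male interaction thus totalled 2686 genes, the rise or fall with time in control males for 5398 rather than 8555, and disruption in late males for 4881 rather than 7596.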

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

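Of the tests in this part, those on sex labels, on a shared background, on depth, on the chance overlap at E6, on a shared difference of E6 libraries and on linkage were chosen only after the result was seen. The sex score moved by 0.983 in late disrupted males and by -0.401 in late disrupted females, each against controls of the same sex, and every disrupted library lay beyond its controls. The effect of disruption differed between the sexes for 7872 genes at the later time and for 22 genes at E6, by the interaction test. It differed between the times for 4030 genes in males and 2069 in females, where the titles of controls and of disrupted females change as well.

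The first pattern is that late disrupted males sit at the level of control females. The tables argue against swapped sexes, since the highest W sum among these libraries was 34.3 CPM, against the series of control libraries without the title suffix, since 7307 genes were called in males with the suffix as a term, and against a background that both sexes share as the whole cause, since male and female disruption folds had an r of -0.448 across autosomal genes. A background acting in males alone stays open. A change of the male gonad toward the female state is a candidate explanation, as a hypothesis. Whether it is a change within cells or of the mix of cells was not tested.

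The second pattern is the fall of female programme genes in late disrupted females. Fewer reads are argued against, since with equal counts per library disrupted minus control females was -1680 detected genes. Thinning evens out reads only, so it cannot decide whether fewer RNA molecules entered these libraries. The choice of genes by the control libraries is argued against, since the lowest mean score of simulated unchanged females was 0.951. These simulations leave out variation shared between genes. An even dilution by other cells is argued against, since 39.8% of the 610 genes at least 16-fold higher in control females were not called lower, while 58.9% were at least 4-fold lower. Loss of a cell type or stage that expresses part of the programme may account for this and stays open.

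The third pattern is the group of genes lower in both sexes at E6. Chance overlap is argued against, with 19 shared genes where 0.425 would be shared. That value takes every gene as equally likely to be called, so it may be too low. In opposite directions, 2 genes were higher in males and lower in females where 0.116 would be shared. The reverse held for 0 genes, where 0.0493 would be shared. A linked chromosome region behind most of the 19 is argued against too, since 2 of them lay within 5 Mb of another where random draws averaged 2.95. That test cannot decide on a few linked genes. The 2 neighbours are among the 4 of the 19 on Z, so a linked region of Z stays open for those 4. A difference between all disrupted and all control E6 libraries stays open: the folds of the sexes had a Pearson r of -0.0851 but a Spearman rho of 0.200 across autosomal genes. An effect of the disruption in both sexes, which the design names, was not tested further for these 19 genes and stays open.

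Other splits of the same samples were counted for each comparison. For comparisons of 3 with 3 libraries, the 10 splits are too few for a share under 0.05, so only the real value and the highest other value are given. In 2 of the 10 splits for disruption in E6 males, the real one with 140 genes included, as many genes were called, and the other called 2501. It set control replicate 1 with disrupted replicates 1 and 3 against disrupted replicate 2 with control replicates 2 and 3, which points to a structure of these 6 libraries that the labels do not give. In each of the other comparisons of 3 with 3, 1 of the 10 splits, the real one, reached its own count. The real and highest other values were 77 and 0 for disruption in E6 females, 386 and 0 for sex in E6 controls, 251 and 0 for sex in E6 disrupted gonads, and 225 and 0 for E6 disrupted males against control females. At the later time they were 7596 and 127 for disruption in males, 4142 and 2 for disruption in females, 6918 and 269 for sex in controls, 5642 and 1 for sex in disrupted gonads, and 468 and 6 for disrupted males against control females. For time they were 8555 and 1347 in control males and 9834 and 0 in control females.

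For the interactions 60 splits were counted. For the late interaction with sex, only the real split of the 60 reached 7872 genes, and the highest other was at 4412. This share alone does not exclude chance, since the split that swaps disrupted and control in 1 whole arm was not drawn. An arm is a sex here and a time in the interactions with time. Such a split called more genes than the real split in the other interactions, with 393 at E6, 4885 for time in males and 2355 in females. It adds up the effects of disruption in both arms, so it is not a split without an effect. It still counts among the splits of those interactions below. In the late interaction with sex, splits with no arm as labelled reached at most 16 genes. At E6 chance was not excluded, with 5 splits of 60 at 22 genes or more and the highest at 1166, many times the real count, which again points to a structure of the E6 male libraries, since that split left the females as labelled. For the interaction with time, 7 of 60 splits in males reached 4030 genes or more, with the highest at 5812, and 3 of 60 in females reached 2069 or more, with the highest at 2521, so by this share chance was not excluded. That share decides little, because the splits that reached these counts left at least the late arm as labelled and so still held the late effect. Splits with no arm as labelled reached at most 1078 genes in males and 0 in females. Any of the 12 libraries left out moved the 22 genes of the E6 interaction by over 1.5 times, to between 6 and 59.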

How the results depend on the processing

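Tests with library sizes only, without mitochondrial genes, with the title suffix (left out or as a term) and with control libraries left out of the scores were chosen after seeing the data. Also not fixed beforehand were all alternatives of the programme counts, the genes lower in both sexes, the correlations and the Z shifts. The same holds for scores under other scalings, without the filter or on the 12 libraries of a time. No named gene, score, correlation or Z shift changed sign under the alternatives run. The balance of higher and lower genes did turn over in some comparisons: sex in E6 controls (179 and 207) with DESeq2 (300 and 276), sex in E6 disrupted gonads (80 and 171) without disrupted female replicate 1 (154 and 112), E6 disrupted males against control females (122 and 103) on the compared groups (54 and 85), the E6 interaction with sex (19 and 3) with DESeq2 (58 and 160), late disrupted males against control females (274 and 194) without control female replicate 1 (370 and 405), and, without mitochondrial genes, the late interaction with sex (4130 and 3742 to 4028 and 4051) and the male interaction with time (2066 and 1964 to 1982 and 2089). Other single libraries left out turned over some of these too. Of 160 counts of changed genes under alternatives other than leaving out a library, 140 stayed within 1.5 times, as did 91 of 120 with a library left out. Of the sex scores, 33 of 44 and 23 of 36 moved by less than the spread between replicates. Of the other values, 115 of 130 and 142 of 180 stayed. Named genes kept their side of the threshold in 156 of 160 and 84 of 96 fits. Gene set tests were not run. No comparison had correlations of same-number replicates above 0.1 in all pairs (-0.03 to 0.43 in E6 males, -0.40 to -0.08 in E6 females). A pairing of some libraries stays open. E6 males had 0.40 and 0.43 for replicates 1 and 2 but -0.03 for 3. E6 disrupted males and females had 0.47 and 0.23 for replicates 2 and 3 but -0.23 for 1. With a replicate block disruption called 129 genes in E6 males, 68 in E6 females, 7319 in late males and 3979 in late females. At these depths and with 3 libraries per group, 33% to 46% of simulated 2-fold changes were recovered, and the part of depth in this was not tested. Except where fewer libraries entered the fit, the cause was not tested.

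Fits on the 12 libraries of a time gave 364 genes for disruption in E6 males, 120 in E6 females, 293 for late disrupted males against control females, 20 E6 female programme genes higher in disrupted males, 60 E6 male programme genes with 49 lower in disrupted males, 34 genes lower in both sexes, an E6 correlation of 0.683 and an E6 female score of 0.884. Fits on the compared groups gave 195 genes for disruption in E6 females, 127 for sex in E6 disrupted gonads, 139 and 275 for disrupted males against control females at E6 and later, 4881 for disruption in late males, 3802 for sex in late controls, 5398 for time in control males and 2686 for its interaction with disruption. DESeq2 gave 501 and 255 genes for disruption in E6 males and females, 481 for sex in E6 disrupted gonads, 395 and 750 for disrupted males against control females at E6 and later, 218 for the E6 interaction, 144 E6 female programme genes with 24 higher in disrupted males and 31 lower in disrupted females, 44 E6 male programme genes lower in disrupted males, and 58 genes lower in both sexes.

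Without the filter on low counts, the E6 interaction had 14 genes, 5 E6 female programme genes were higher in disrupted males, the correlations were 0.527 at E6 and 0.860 later, the E6 Z shift in controls was -0.42 (-0.419) and the late male score was 0.958. Without the libraries lacking the title suffix, 1042 genes separated late disrupted males from control females, the late Z shift was -0.69 (-0.687) and the late scores were 0.958 in males and 0.653 in females. With the suffix as a term these were 914 genes, 1.00 and 0.574. The late female score was 0.619 with library sizes only, 0.545 with sex-biased genes of any fold and 0.582 with a prior count of 0.5. On genes sex-biased at both times the late scores were 1.01 in males and 0.851 in females.

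With each library left out in turn, disruption called 40 to 267 genes in E6 males and 31 to 80 in E6 females, sex in E6 controls 246 to 299, the E6 interaction 6 to 59, and late disrupted males against control females 257 to 775. The E6 female programme held 45 to 92 genes, with 0 to 9 higher in disrupted males and 7 to 22 lower in disrupted females, and the E6 male programme 17 to 52, with 11 to 39 lower in disrupted males. Genes lower in both sexes were 7 to 19. The correlations ran from 0.502 to 0.657 at E6 and from 0.898 to 0.933 later. Scores ran from 0.697 to 0.819 in E6 males, 0.739 to 0.891 in E6 females, 0.925 to 0.979 in late males and 0.554 to 0.665 in late females. The Z shift in controls ran from -0.541 to -0.421 at E6 and from -0.900 to -0.745 later.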

Other observations

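A distal part of the Z chromosome, between 74 and 79 Mb with 46 tested genes, showed a strong sex difference among late disrupted gonads. Of the 46 genes, 44 were lower in disrupted females than in disrupted males, with a median log2 fold of -5.41, or -4.78 with 12 genes at 0 counts at their bound. In control gonads of that time 22 were lower and 3 higher in females. With age 40 of the 46 rose in control males and 23 in control females. Against control females, 11 of the 46 fell in late disrupted females and 35 were not called, and the interaction of disruption with sex was called for 20. At E6 the folds of disruption pointed the other way: none of the 46 was called in either sex, but the median log2 fold was 1.35 in females and 2.12 in males, with 6 and 2 genes negative. These E6 medians are fitted folds without bounds over genes of which most had few or no counts, so their size is uncertain. The median level at E6 was 0 in every control library, and 0.0532 ± 0.0140 CPM in disrupted females and 0.0602 ± 0.0293 CPM in disrupted males (SD, n = 3; exact permutation p of 0.1 in each sex), while the sum did not separate them (exact permutation p of 0.9 in females and 0.4 in males). In late males 4 of the 46 were higher with disruption and none lower. At the later time the summed level of the region did not separate disrupted from control females, at 52.7 ± 4.13 and 54.5 ± 9.60 CPM (SD, n = 3), with an exact permutation p of 0.8. The median level over the 46 genes was 0.0147 ± 0.0255 and 0.201 ± 0.200 CPM (SD, n = 3), with an exact permutation p of 0.1. The region was chosen after its values were seen, and the median was added after the sum had shown no difference, so neither the region nor the median is independent evidence. A few abundant genes carry the sum and most of the 46 have few counts. The end of the chicken Z is known for an array of near-identical gene copies, where reads shared between copies make counts uncertain.

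Chromosomes did not take equal parts in the changes of late disrupted females. On chromosome 7, 169 of 598 genes (28.3%) were lower, against 15.7% elsewhere (adjusted Fisher's exact p of 1.29e-12). On chromosomes 2 and 3 both shares were 19.2%. Low shares were found on many small chromosomes, namely 16, 23, 25, 26, 27, 28, 30, 31, 32 and 33, from 1.15% on 31 to 9.26% on 26. The adjusted Fisher's exact p was at most 0.00567 on each of these chromosomes, 2 and 3 included, and on W, where 0 of 81 genes were lower. With an adjusted p above that value but under 0.05, the share was high on chromosomes 1, 4 and 10. It was low on 15, 17, 20, 24 and Z. Chromosomes 23 and 33 also had few higher genes in late disrupted males, at 12.5% and 10.2% (22.7% elsewhere for each). That share was low too on 16, 18, 24, 25, 28, 30, 31, 32 and W, each at an adjusted Fisher's exact p under 0.05. By the same threshold it was high on 1, 2, 5 and 7. Neighbouring genes are not independent, and no explanation was tested.

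A hypothesis for the loss in late disrupted females is that it falls on the part of the female programme that comes up between E6 and the later time. The test, written before its result was seen, asked for a difference of over 20 percentage points and used disrupted males, whose libraries do not define the programme and whose titles, unlike those of controls and disrupted females, do not change between the times. Genes that rose with age in disrupted males made up 81.3% of the 1389 lost genes and 58.6% of the 1386 others, a difference of 22.7 percentage points (Fisher's exact p of 2.47e-39, with genes not independent). This passed narrowly. In strata of expression the difference kept its sign, but only the low stratum (85.2% and 57.9%) was past 20 points, and the middle (80.8% and 61.8%) and high (74.5% and 56.4%) strata fell short. In control males the genes lower in late disrupted females, over all genes tested, rose with age no more often (32.4%) than the genes that were higher (35.1%). Of all genes tested, 26.1% rose there. Of the 1176 genes at least 8-fold lower, 40.3% rose, and genes at least 8-fold higher were not set against age. Within the female programme, 355 of the 1389 lost genes (25.6%) and 187 of the 1386 others (13.5%) rose with age in control males. Those libraries help define the programme, and their titles change between the times. On genes sex-biased at both times, the female score was 0.851 rather than 0.599, but this rests on 55 of the 2775 female and 26 of the 1305 male programme genes, and 14 of the 55 were among the lost genes. The overall share in disrupted males met the prediction, and the programme genes went the same way in control males. The wider comparison in control males, over all genes tested, did not set lower genes above higher ones, though both rose more often than all genes tested. Genes at least 8-fold lower rose more often still, but without a like set of higher genes beside them this decides nothing. The hypothesis was found and tested on the same libraries, so it stays open.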
